A study of Homo sapiens with 6 samples.

How the data were processed

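Total RNA of HCT116 cells, an established human colorectal carcinoma line, was measured on whole-transcript expression arrays after biotin labelling with a whole-transcript kit, per the labels' protocols. The 6 arrays fell into 2 groups of 3: cells stably transduced with an empty vector (control), and cells labelled as overexpressing miR-196b. Some labels spell the cell line and the microRNA differently, and the groups were taken from the titles and genotype fields, which separate the same arrays. The labels call the arrays of a group biological replicates and do not say whether each came from its own transduction, so p-values measure the spread between these cultures. The number of arrays limits the precision.

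The deposited values are on a log2 scale, 1 value per probe set and array. RMA and Partek 6.6 are named in the submitters' processing notes, with no order or options. RMA includes a background correction and a quantile normalization between arrays, which removes any difference in overall level between the groups. The log base was taken as 2 because RMA gives log2 values. The 6 arrays had medians of 4.34 to 4.37 and maxima of 14.1 to 14.2, and no array repeated the values of another. No genome build is named in the sources used here.

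Genes were named through the platform annotation given with the values, with symbols updated through gene identifiers to those of the GRCh38.p14 annotation, which served for names, biotypes and chromosomes only. Of 53617 probe sets, 16098 were paired with 1 gene symbol (14884 genes), 0 with several, and 37519 had no symbol here and were treated as unnamed, not as lacking a gene. Probe positions within a gene were not used here. The array measures precursor transcripts of microRNAs, not the mature microRNA.

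All computation was done in R 4.3.3 with limma 3.58.1. The deposited values were fitted without further normalization or filter with lmFit and eBayes, with no trend and no robust fit, on the 16098 named probe sets. Fold changes are those of the arrays labelled miR-196b minus control, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. With 4 residual degrees of freedom, the fit added 3.23 prior degrees of freedom. Intervals are 95% intervals from the same fit. An exact two-sided permutation test of 3 against 3 arrays cannot give a p below 0.1.

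Gene lists were fixed before the data were examined. Of the 22 lists, 21 had at least 2 measured members and were tested with camera in limma, at a preset correlation of 0.01 and with the brightest probe set of each gene. The list of histone genes had too few measured members for a test. The same lists were tested with fry and with an estimated correlation, and adjusted p-values cover the 21 lists. A list of genes carrying a miR-196b seed match in the 3 prime UTR was planned and not run, because no transcript sequences were used here.

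The named genes followed a rule fixed before the data were examined. It took MIR196B, HOXB7 and GALNT5. It also took the 10 largest rises and the 10 largest falls among protein-coding and similar genes past the threshold with separated groups, with free places filled by the smallest unadjusted p and described as not past the threshold. From each list it took up to 4 members with the smallest p. Small RNAs, antisense and LINC RNAs, pseudogenes, uncharacterised loci and olfactory receptors were left out of the largest changes. MIR196A2, MIR196A1 and MIR149 were named after their values were seen.

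The fit was tested on simulated data with 16098 genes. Of 50 genes changed per fold size, it recovered 8% at 1.25-fold, 58% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, with 11 false calls. All fold sizes were planted in the same data, and the adjusted threshold is easier to pass when more genes change. With 9 calls in the real arrays, these shares are likely too high for them. Of 200 simulated lists of 20 genes, camera gave a p below the threshold for 3.5% without a shift and for 100% with a shift of 0.25 on the log2 scale. Simulated genes varied independently, so neither share covers lists whose members vary together. Estimated correlations reached 0.27 in the lists tested here (cholesterol synthesis). The shift tried was also larger than the median change of any called list.

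The alternatives were a filter leaving out the dimmest 40% of probe sets, a variance prior with trend and robust fit, median centring, a repeated quantile normalization, array weights, a fit with the replicate number as a block, each array left out in turn, all probe sets of the array, no variance moderation, an estimated correlation, and the mean of a gene's probe sets. Others were added after the data were seen. No slide or scan date was used here, so no batch was tested.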

Results

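Expression was compared between HCT116 cells labelled as overexpressing miR-196b and cells carrying an empty vector, with 3 arrays in each group. The title of the series ties this microRNA to cell migration through HOXB7 and GALNT5. The arrays correlated at r = 0.994 to 0.995 within a group and at 0.992 to 0.994 between groups, across probe sets, which are not independent replicates. The first principal component held 28.9% of the variance and separated the groups. The second held 19.7% and set labelled replicate 1 (18.4) and labelled replicate 3 (-12.9) apart, with the other 4 arrays between -3.49 and -0.035. The median within-group SD of a probe set was 0.128 on the log2 scale.

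GALNT5, an enzyme that starts mucin-type O-glycosylation, fell in the arrays labelled miR-196b. Its level was 7.84 ± 0.149 in control and 6.75 ± 0.0514 in the labelled arrays (log2, SD, n = 3 each). That is a log2 change of -1.09 with an SE of 0.09, or 2.13-fold lower (limma adjusted p = 0.0233). HOXB7, a homeobox transcription factor, was at 8.02 ± 0.0749 in control and 7.38 ± 0.0710 in the labelled arrays (log2, SD, n = 3 each). Its log2 change was -0.64 with an SE of 0.08 (1.55-fold lower), which did not pass the test (limma adjusted p = 0.0974). The probe set of MIR196B, the gene the labels name, was at 7.97 ± 0.102 in control and 8.05 ± 0.144 in the labelled arrays (log2, SD, n = 3 each). Its log2 change was 0.08 with a 95% interval of -0.16 to 0.31 (limma adjusted p = 0.819). All 3 control arrays lay above all 3 labelled arrays for GALNT5 and for HOXB7, where the exact permutation p was 0.1, the smallest that 3 against 3 arrays can give. The GALNT5 call ended with any of the 6 arrays left out (adjusted p = 0.0519 to 0.179 in limma) and with all 53617 probe sets tested (0.0746), over a range of 3.6e-05 to 0.179 across all alternatives. HOXB7 passed without the dimmest 40% of probe sets (adjusted p = 0.0164) and with a trended, robust variance prior (0.00146), over a range of 0.00146 to 0.486 across all alternatives.

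The MIR196B probe set did not show a rise. Its probes may lie outside the expressed part, so this does not decide whether the labels hold. Directions below are those of arrays labelled miR-196b. MIR196A2, another gene of the microRNA family, was examined after its values were seen. Its probe set rose from 3.06 ± 0.167 in control to 10.6 ± 0.149 in the labelled arrays (log2, SD, n = 3 each), a log2 change of 7.55 with an SE of 0.12, or 188-fold in measured signal (limma adjusted p = 4.53e-07). Its control level was not tested against background, so this is no exact fold of the transcript. MIR196A1, the third gene of the family, had a log2 change of -0.27 with an SE of 0.17 (limma adjusted p = 0.622). The array reads precursor transcripts, so these values give no level of the mature microRNAs.

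**Figure D1:**
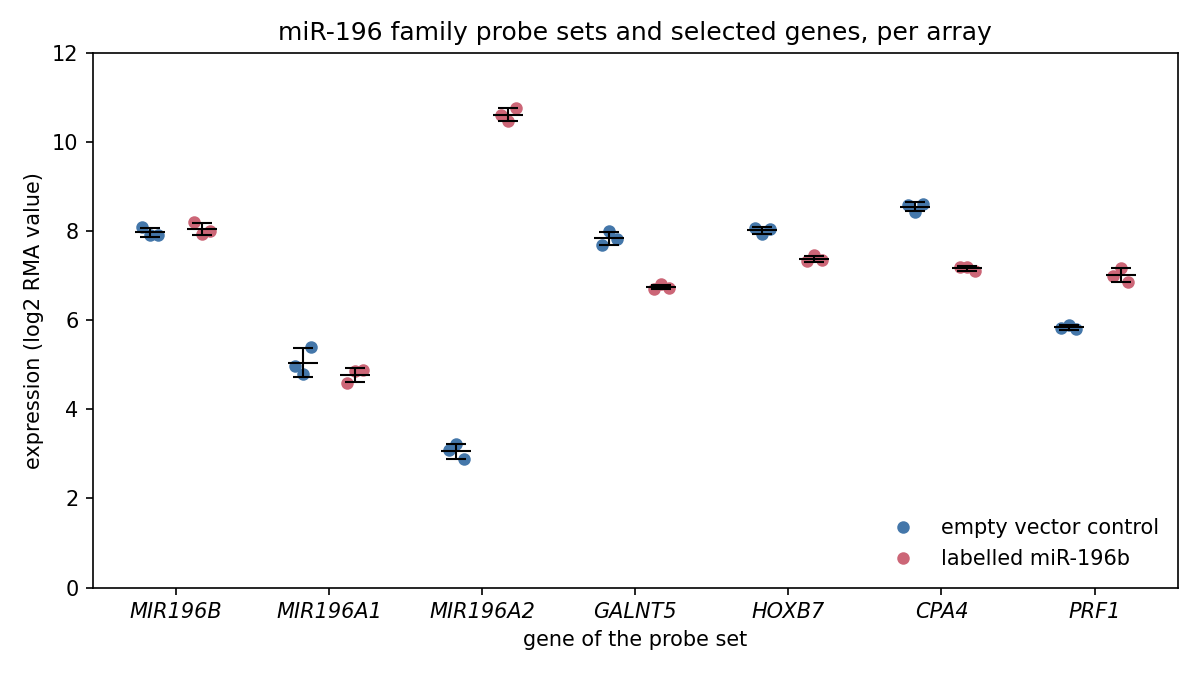
Expression of 7 probe sets (log2 RMA value, vertical axis) by gene (horizontal axis), with a point per array, and the mean and SD of 3 arrays as bars, for empty vector control (blue) and arrays labelled miR-196b (red). MIR196B overlaps between the groups at means of 7.97 and 8.05, while MIR196A2 lies at 3.06 and 10.6.

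Of 16098 named probe sets, 9 changed, 4 higher and 5 lower in the arrays labelled miR-196b, and all 9 by at least 1.5-fold (limma, adjusted p below 0.05). Beside MIR196A2, the probe sets that rose were PRF1, which encodes the pore-forming protein perforin, SAT1, an enzyme of polyamine breakdown, and NFIB, a transcription factor. Their log2 changes were 1.17 for PRF1 (2.25-fold, adjusted p = 0.0233), 0.85 for SAT1 (1.80-fold, 0.0452) and 0.67 for NFIB (1.59-fold, 0.0452). PRF1 went from 5.84 ± 0.0562 to 7.01 ± 0.158 (log2, SD, n = 3 each). The probe sets that fell were CPA4, a carboxypeptidase, KRTAP2-3, a keratin-associated protein, GALNT5, DKK1, a secreted WNT antagonist, and MIR149. CPA4 fell by 1.38 on the log2 scale (2.60-fold, adjusted p = 0.00338), from 8.55 ± 0.0988 to 7.17 ± 0.0526 (SD, n = 3 each). KRTAP2-3 fell by 1.26 (2.40-fold, adjusted p = 0.0233), DKK1 by 0.83 (1.77-fold, 0.0233) and MIR149 by 0.75 (1.68-fold, 0.0480). MIR149 was named after its values were seen, and its host gene GPC1 had log2 changes of -0.16 and -0.18 at its probe sets, neither past the threshold. KRTAP2-3 has near-identical copies whose signal the probes could share, and these had log2 changes of -0.31 (KRTAP2-4), 0.04 (KRTAP2-1) and -0.13 (KRTAP2-2), so its value is uncertain.

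The other genes taken by the naming rule did not pass the test. On the higher side, in order of p, these were TANK, an adaptor of NF-kB signalling (log2 change 0.67, adjusted p = 0.0975), TMT1A (0.77, 0.102), the cadherin FAT4 (0.69, 0.144), the splicing regulator MBNL3 (0.98, 0.144), DENND5B (0.48, 0.144), CNTNAP3 (0.66, 0.144) and the mast cell tryptase TPSAB1 (0.55, 0.160). A further probe set of CNTNAP3 had a log2 change of 0.56 and its near-identical copy CNTNAP3B 0.57, while TPSB2, close to TPSAB1 in sequence, had -0.03. On the lower side were KRTAP3-1 (-1.29, adjusted p = 0.0528), the annexin ANXA10 (-0.93, 0.0586), HOXB7, CCDC106 (-0.67, 0.160), the RNA GAS6-DT (-0.73, 0.160) and the zinc finger factor ZNF750 (-0.57, 0.160).

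At an unadjusted p below 0.05, 1589 probe sets passed, 923 higher and 666 lower, and 68 of these by at least 1.5-fold. The groups were separated at 2772 probe sets, or 17.2%, where chance gives 10%. With any of the 6 arrays left out, 2 to 3 probe sets were called and only CPA4 and MIR196A2 of the 9 kept their call. Without variance moderation CPA4 lost its call too and MIR196A2 alone of the 9 kept it, and across all alternatives the adjusted p of CPA4 ranged from 6.7e-07 to 0.12. SAT1 and MIR149 lost theirs with a repeated quantile normalization, and 7 of the 9 lost theirs with all probe sets of the array tested. More passed without the dimmest 40% of probe sets (22, 12 higher and 10 lower). With a trended, robust variance prior 91 passed, 56 higher and 35 lower.

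**Figure D2:**
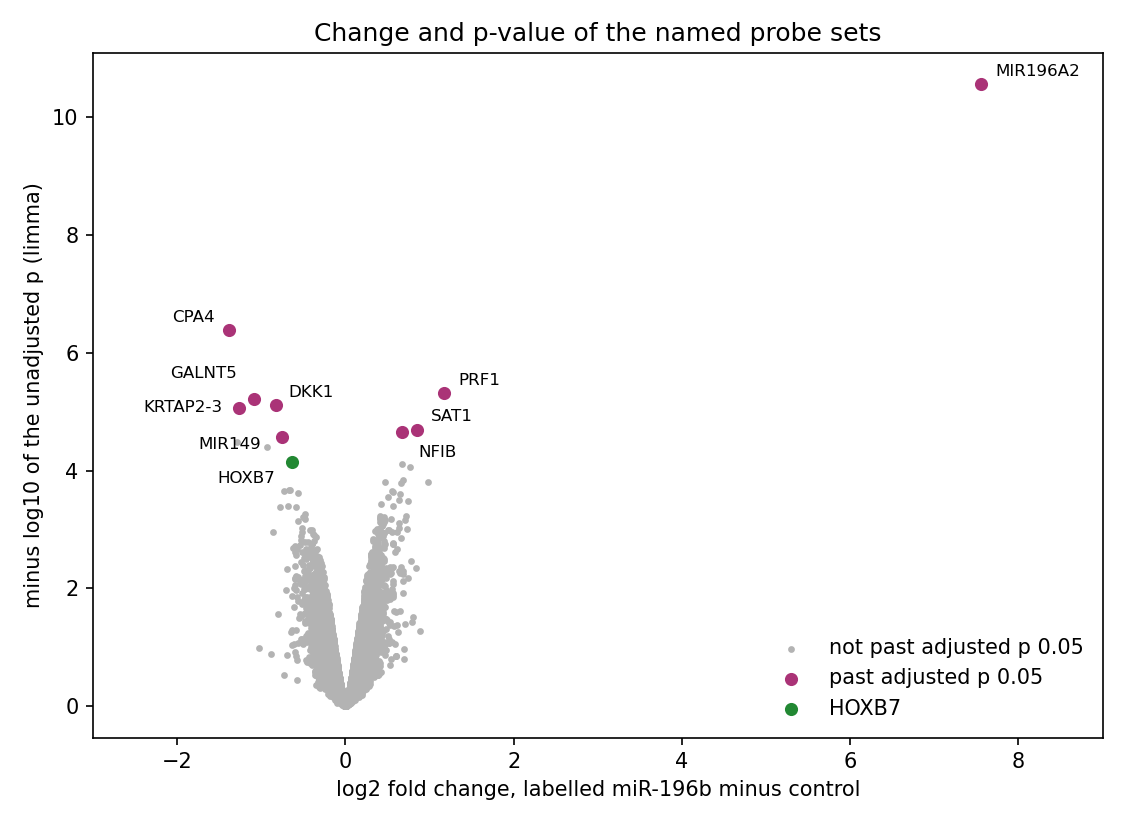
Log2 fold change of the arrays labelled miR-196b minus control (horizontal axis) against minus log10 of the unadjusted limma p (vertical axis) for 16098 named probe sets, with those past an adjusted p of 0.05 in purple and HOXB7 in green. MIR196A2 lies apart at 7.55, and the other called probe sets lie between -1.38 and 1.17.

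Among 21 gene lists fixed before the data were examined, 4 shifted by camera, and all 4 were also called by fry. Fry used the same arrays and asks whether members change, not whether they change more than other genes, so it is no separate support. Hypoxia and glycolysis genes rose as a list: 17 of 20 measured members were higher and 3 lower, with a median log2 change of 0.12 (camera adjusted p = 0.00490, and adjusted p = 0.228 with an estimated correlation). NDRG1, a hypoxia-induced gene (0.42), and BNIP3L, a mitophagy receptor (0.32), passed when adjusted over the list alone, and 0 members passed over all genes. ADM, the peptide hormone adrenomedullin (0.35), and KDM3A, a histone demethylase (0.28), passed neither. The p53 targets fell as a list, with 12 of 16 members lower and a median of -0.09 (camera adjusted p = 0.0118, and adjusted p = 0.228 with an estimated correlation). The pro-apoptotic gene BAX (-0.30) and the kinase gene PLK2 (-0.45) passed adjusted over the list alone, TRIAP1 (-0.39) and TIGAR (-0.27) did not, and 0 members passed over all genes.

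Reported miR-196 targets fell as a list, with 9 of 15 measured members lower, 6 higher and a median of -0.15 (camera adjusted p = 0.00957, and adjusted p = 0.228 with an estimated correlation). Without GALNT5 and HOXB7, a test chosen after the data were seen, the list was not called (adjusted p = 0.304). GALNT5, HOXB7 and HOXB8 (-0.47) passed adjusted over the list alone, ANXA1, an annexin (-0.22), did not, and GALNT5 alone passed over all genes. This list holds 23 genes, so part of it was not measured, and HMGA2 (0.24) and HOXC8 (0.08) were among the 6 higher members. The series title names GALNT5 and HOXB7, so the list is not independent evidence of its direction. HOX genes, which set position along the body axis, fell as a list, with 17 of 27 measured members lower and a median of -0.10 (camera adjusted p = 0.0210, and adjusted p = 0.228 with an estimated correlation). The list holds 39 genes, and of the HOXA cluster HOXA2 alone was measured (0.17). Without the reported miR-196 targets, a test chosen after the data were seen, the HOX list was not called (adjusted p = 0.279). HOXB7 and HOXB8 passed adjusted over the list alone, HOXB4 (-0.32) and HOXD1 (-0.29) did not, and 0 members passed over all genes. All 4 lists lost their call without replicate 1 of the labelled arrays (adjusted p = 0.0555 for the hypoxia, p53 and target lists and 0.102 for HOX genes), and HOX genes without control replicate 2 (0.0588).

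**Figure D3:**
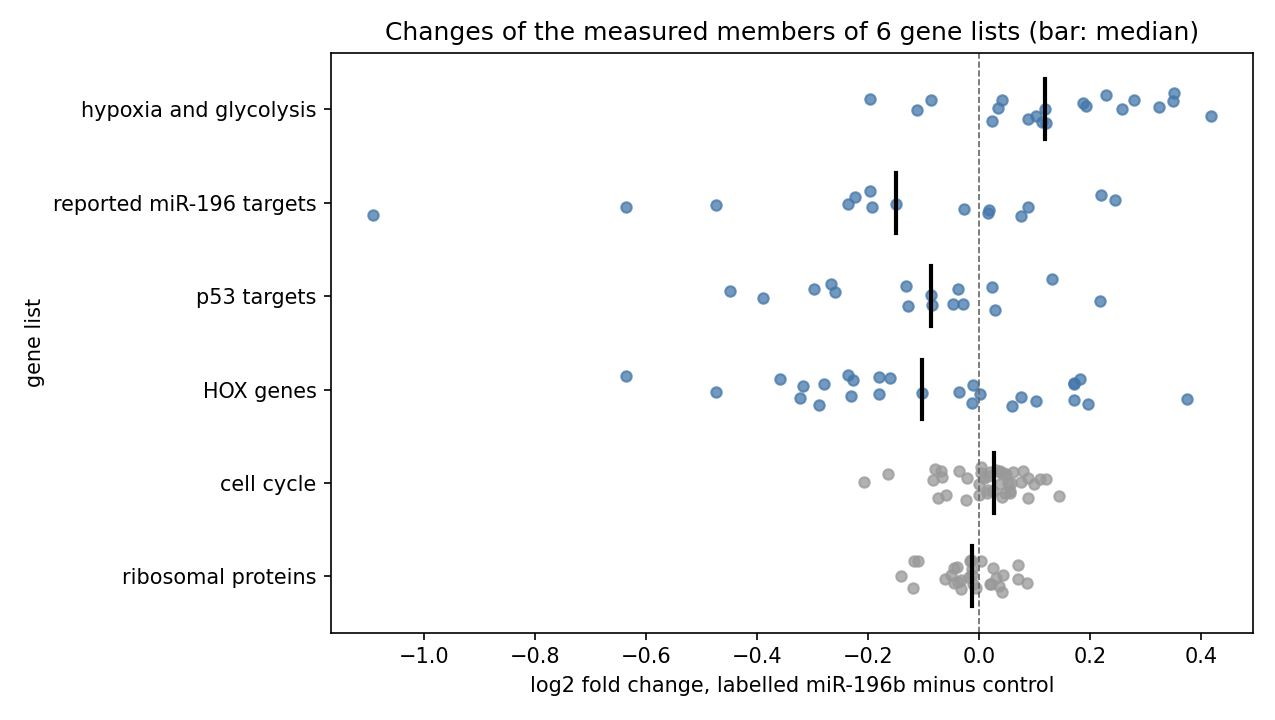
Log2 fold change of the arrays labelled miR-196b minus control (horizontal axis) of each measured member of 6 gene lists (vertical axis), with a point per gene and the median as a bar, for the 4 lists called by camera (blue) and 2 lists that were not (grey). The medians lie at 0.12 for hypoxia and glycolysis, -0.15 for reported miR-196 targets, -0.09 for p53 targets and -0.10 for HOX genes.

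The other 17 lists were not called (camera adjusted p = 0.175 to 0.849). A fry test for members changing in either direction passed for the WNT, MAPK, GALNT, epithelial, adhesion, mesenchymal and let-7 lists (adjusted p = 1.6e-05 to 0.012). That test asks whether members change at all, not whether they change more than other genes. In the GALNT family, 11 of 20 members were higher and 9 lower, and GALNT5 alone passed, over the list and over all genes; GALNT13 had a log2 change of -0.42 and GALNT12 of 0.17. The family's median was 0.0039 and its mean -0.06, so they differ in sign (camera adjusted p = 0.651). The let-7 targets had 14 of 20 members lower (adjusted p = 0.175), among them THBS1, an extracellular matrix protein (-0.48, past the test over the list alone), and GEMIN7 (-0.26). IGF1R (0.22) and HMGA2 (0.24) were among the 6 higher members. In the small RNA machinery list, TNRC6B had 0.19 and LIN28B -0.19, and 0 of 10 members passed (adjusted p = 0.656).

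WNT targets split, with 9 of 21 members higher and 12 lower (camera adjusted p = 0.651). DKK1 passed over all genes, and RNF43, a ubiquitin ligase that dampens WNT signalling (0.38), and BMP4 (0.31) passed adjusted over the list alone, opposite to DKK1. Among immediate early and MAPK output genes, SPRY4 (0.46), DUSP6 (0.47), both feedback inhibitors of the pathway, and ETV1 (0.41) were higher and FOSB lower (-0.30), each past the test over the list alone, while 17 of 27 members were lower (adjusted p = 0.656). In the adhesion and matrix protease list, ADAM19 (0.45) and MMP14 (0.32) were higher and THBS1 lower (-0.48), each past the test over the list alone, and 12 of 18 members were higher (adjusted p = 0.651). Of 17 mesenchymal genes, 10 were higher and 7 lower (adjusted p = 0.656). FN1, which encodes fibronectin, passed over the list alone (0.56), while ZEB1 had 0.39 and PRRX1 -0.32. Epithelial junction and keratin genes went both ways, with CGN at -0.59, TJP3 at 0.50 and KRT18 at -0.22, and 0 of 28 passed (adjusted p = 0.656).

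No member of the remaining 9 lists passed over its list alone. Cell cycle genes had 30 of 42 members higher (median 0.03, camera adjusted p = 0.661), with CCNE1 at -0.21. ATF4 and unfolded protein response genes had 13 of 20 higher (adjusted p = 0.279), with DDIT4 at 0.57. Interferon response genes had 13 higher and 13 lower (adjusted p = 0.656), with ISG15 at -0.28, and TNF and NF-kB response genes had 7 higher and 10 lower (adjusted p = 0.849), with LIF at 0.26. Cholesterol synthesis genes had 10 of 17 higher (adjusted p = 0.656), with STARD4 at 0.23. Colon differentiation genes had 11 higher and 12 lower (adjusted p = 0.612), with KRT20 at -0.33 and CDX2 at -0.26. Ribosomal protein genes had 19 of 30 lower (adjusted p = 0.651), with RPL35 at -0.14. Of markers of other cell types, 6 fibroblast genes had 2 higher and 4 lower (adjusted p = 0.839), with LUM at 0.18 and THY1 at -0.16. The 6 blood cell genes had 3 higher and 3 lower (adjusted p = 0.770), with CSF1R at 0.31 and CD68 at -0.20.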

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

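The tests of MIR196A2, of the unnamed probe sets, of the target list and of the 1.5-fold count were chosen after the results were seen, and the splits for all calls and for the lists were set before.

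Probe sets with no symbol here entered no fit above other than those of all probe sets. In a limma fit of all probe sets, 2 of them were called higher in the arrays labelled miR-196b (adjusted p below 0.05). These were 17118492, by 8.09 in log2 signal, and 16793142, by 1.499, with control levels not tested against background. In the same fit, 10 unnamed ones passed, with 7 distinct sets of values, 2 higher and 8 lower. Probe set 17118492 went from 3.22 ± 0.198 to 11.3 ± 0.224 and 17118488 from 12.8 ± 0.0600 to 5.51 ± 0.304 (log2, SD, n = 3 each). Of the 6 that differed by over 32-fold, 1 was higher (8.09) and 5 were lower (3 distinct sets of values, each at -5.98 or below), which argues against a shift of whole arrays left by the normalization and against a transcript carried by only 1 vector as the source of all 6, since either would move them the same way. Different sequences carried by each vector may account for them (smallest absolute log2 change 5.98), but without probe sequences this cannot be told apart from a change in the cells. If the vectors differ so, the groups differ in more than the microRNA. The changes of named genes and lists could then not be told apart from effects of the vectors.

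The MIR196A2 signal rose 188-fold, from a control level not tested against background, while MIR196B had a log2 change of 0.08. A gap of 7.25 on the log2 scale between the lowest labelled and the highest control array argues against an exchange of single arrays. An exchange of the whole groups would place the 188-fold higher MIR196A2 signal in the cells with the empty vector. Such an exchange was not tested and stays open. GALNT5 (-1.09), HOXB7 (-0.64) and HOXB8 (-0.47) were lower in the labelled arrays, the direction that overexpression would give reported targets. The series title names GALNT5 and HOXB7, so their fall cannot decide this. Of the 15 measured targets 6 were higher, HMGA2 (0.24) among them. Higher transcription of the surrounding HOXC genes is argued against by their upper 95% limits, the largest of which was 0.82 over 7 genes. A MIR196B hairpin read by the MIR196A2 probes through shared sequence may account for it, but the upper limit of 0.31 for MIR196B does not decide this, because the MIR196B probes may lie outside the expressed part. The MIR196A1 probe set, of the same family, did not rise (-0.27, 95% interval -0.66 to 0.12). Which sequence its probes share with the other 2 genes was not examined, so this does not decide it. Whether the vector held a MIR196A2 hairpin stays open as untested.

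The reported miR-196 target list fell by camera at the preset correlation, a call lost with an estimated correlation (adjusted p = 0.228). The call may rest on the genes the study names, since without GALNT5 and HOXB7 the camera p was 0.087 over 13 genes. The call did not need the dim members, since the 7 members in the brighter part of the array gave a camera p of 5.1e-04. These include GALNT5 and HOXB7, so this p does not tell whether the other members fell. A fall of the HOXB locus as large as that of HOXB7 is argued against by a median of -0.14 for 8 other HOXB genes, above the upper limit of -0.45 for HOXB7, and a smaller shared shift stays open. An effect of the transduced microRNA stays open as untested.

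The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 9 probe sets and the highest other 0, and likewise 9 and 0 at 1.5-fold or more, so that only the real split, 1 of the 10, gave counts as large. It called 4 gene lists, where the highest other split called 2, again the only 1 of the 10 with as many.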

How the results depend on the processing

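The fits of named genes over all probe sets, the lists with members left out (reported targets without GALNT5 and HOXB7 or with brighter members only, HOX genes without the targets) and the count with repeated values taken once were chosen after the data were seen; the other alternatives were set before. The cause of a change was not tested unless given here. Without the dimmest 40% of probe sets, 22 probe sets passed, 12 higher and 10 lower (17 at 1.5-fold or more), and HOXB7 passed at -0.64. Fewer were tested there and the variance prior was refitted, and the effects of these were not told apart. With a trended, robust prior 91 passed, 56 higher and 35 lower (27 at 1.5-fold or more), HOXB7 again at -0.64. Without variance moderation 5 passed (1 at 1.5-fold or more), MIR196A2 alone of the 9 kept its call, CPA4 lost it, and GALNT5 did not at -1.09 (adjusted p = 0.165). Over all probe sets of the array, where more are tested and the prior is again refitted, GALNT5 did not pass at -1.09, and 12 passed, or 9 with repeated values once. Median centring gave 9, array weights 11 and a repeated quantile normalization 7. The replicate numbers did not pair the arrays (correlations of deviations 0.030, 0.037 and 0.0085); with the replicate block 1 passed (1 at 1.5-fold or more), MIR196A2, so CPA4 did not, and GALNT5 was at -1.09 (adjusted p = 0.124), while the 4 lists kept their calls.

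With fewer arrays, leaving each out gave 2 to 3 called probe sets (2 to 3 at 1.5-fold or more), GALNT5 at -1.16 to -1.01 and MIR196B at -0.00073 to 0.14, reversed without replicate 1 of the labelled arrays. FBLN1 ranged from -0.056 to 0.21 and TYROBP from -0.090 to 0.13. Called lists numbered 0 to 4, with adjusted p of 0.0078 to 0.0555 (reported targets), 0.0088 to 0.102 (HOX), 0.0088 to 0.0555 (p53) and 0.0031 to 0.0555 (hypoxia). Lists that were not called and changed direction in some of these fits ranged from 0.449 to 0.999 (small RNA machinery and blood cells), 0.629 to 0.999 (mesenchymal), 0.373 to 0.999 (cell cycle), 0.488 to 0.988 (TNF), 0.11 to 0.999 (cholesterol), 0.666 to 0.999 (fibroblast), 0.262 to 0.858 (interferon), 0.373 to 0.858 (WNT) and 0.11 to 0.858 (MAPK). With an estimated correlation 0 lists passed, each of the 4 at 0.228, with unadjusted camera p of 0.016 (hypoxia) to 0.043 (reported targets). The estimate was below the preset 0.01 for hypoxia (-0.017), p53 (-0.046) and HOX genes (0.0033). A higher correlation therefore does not account for the loss of these calls, and the loss is no sign that members vary together. The test with an estimate differs in more than the correlation it uses, and what else differs was not examined. For the reported targets the estimate was 0.034, and whether it accounts for the loss there was not tested. The targets without GALNT5 and HOXB7 gave 0.304, those with brighter members only 0.0053 and HOX genes without the reported targets 0.279. The planned seed-match list was not run, for want of transcript sequences. Signal over background was not used here, so it is unknown which dim probe sets lie at background.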

Other observations

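The values of classes of RNA and the test of HOX genes beyond the reported targets were chosen after the results were seen, and that of chromosomes was set before, except for its deciding value.

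The 14 probe sets in the small nuclear RNA class of the annotation were all of the SNAR genes, a family of small noncoding RNAs. They were lower in the arrays labelled miR-196b at 14 of 14, with a median log2 change of -0.17, and -0.16 with the arrays centred on their median and -0.16 with a repeated quantile normalization. The 14 hold 10 distinct sets of values for 8 gene symbols, so they are not 14 separate measurements, and no test was run on the class. SNAR-H had a log2 change of -0.41 and SNAR-G2 of -0.37, neither past the threshold. The 1236 microRNA probe sets had a median of -0.0035, with 610 higher and 626 lower. Its sign turned with median centring (0.0054). KRTAP3-1, a keratin-associated protein gene, had -1.29, while its relatives KRTAP3-2 and KRTAP3-3 had 0.08 and -0.25. The relatives were dim in control, at 2.54 and 2.13 against 5.75 for KRTAP3-1 (log2), so a fall as large may not show there.

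HOX genes that are not reported targets may have fallen too. The HOX list without those targets gave a camera p of 0.072 over 23 genes, with a median of -0.04. A p of 0.05 or more had first been written down as speaking against such a fall, and this was set aside once the p was seen, because a p over the threshold excludes nothing. The question stays open.

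A difference in copy number of whole chromosomes between the transduced cells could shift the genes of a chromosome together. The largest absolute median log2 change of the 23 chromosomes was 0.038, which argues against a change of a whole chromosome in most cells. By camera 0 chromosomes passed (smallest adjusted p = 0.811). The deciding value was at first the smallest adjusted p and was replaced by the median after both were seen. Smaller segments, or a change in few cells, stay open.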
